A study of Arabidopsis thaliana with 4 samples.

How the data were processed

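Total RNA from leaf discs, extracted with TRIzol per the labels' protocols, was biotin-labelled and hybridized to Affymetrix ATH1 arrays, 4 in all, with 2 control and 2 DTT arrays described as biological replicates per the labels. The authors deposited 1 linear intensity value (signal) per probe set and array. These were made with MAS5 per the submitters' processing notes; the version, probe-level settings and detection calls are not given in the sources used here. On each array the deposited values had a mean of 100 after trimming 2% at each end, so every array had been scaled to one level by the authors. Such scaling sets the mean change near 0 and cannot show a change of total mRNA. MAS5 signals are noisiest when low, which a filter and a variance trend were meant to take up.

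Groups and replicate numbers came from the sample titles. All columns of per-array values were used. Signals of 0 were set to 0.1, the smallest positive value, and log2 was taken with no further normalization. The 64 Affymetrix control probe sets were used for quality checks only. Of the other 22746, those with a mean log2 signal under the 40th percentile (4.08) were left out, which left 13648. Differences were tested with lmFit and eBayes with a mean-variance trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2 scale of the signals, as DTT minus control, and SEs are those of the block fit. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

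Gene names came from the platform annotation supplied with the values. Of the non-control probe sets, 13513 had 1 gene, 503 had several and 8730 had none listed, and no name was given to the last 2 kinds. Of those with 1 gene, 13436 matched a locus of the RefSeq gene table, used for names only. For list tests each gene was represented by its probe set with the highest mean, giving 7300 genes. Because of the sparse annotation, 56 of 393 members of the 25 lists fixed beforehand had a probe set of their own and 6 of the lists had the 3 tested members that a set test needed. A further 17 lists were written after the annotation, the signal distribution of each array and the Affymetrix control probe sets, ribosomal RNA among them, had been read, and before any gene was tested. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted within the 6 and within the 17. List medians within a replicate were set against 10000 random lists matched on mean signal in 20 bins.

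The design, the alternatives named at the end of this section, the 25 lists and the naming rule were fixed before the data were examined. The 17 further lists and the alternatives joined with the block were not. The rule named the 12 largest rises and 12 largest falls with an adjusted p under 0.05 and both DTT arrays beyond both control arrays, up to 4 members past the test per list or the 2 of smallest p where none passed, and the reference genes. Because the fit without a block called none, the rule was applied to the fit with the replicate number as a block, which was decided after that result was seen. The labels do not say that equal numbers mark a shared batch; the hybridization controls separated the arrays by number. Across tested probe sets, the difference between replicates in the control correlated at 0.746 with that in DTT.

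The fits were tested on simulated data, in 40 runs with the real means, replicate shift and residual spread, 13648 probe sets and 200 changes for DTT against control. Without the block 0% of changes were called at log2 changes of 0.5, 1, 1.5 and 2. With the block 5.70%, 54.5%, 92.8% and 98.8% were called, 11.0% of all calls were false, and the highest share in a run was 22.9%. A list of 30 genes shifted by 0.4 was called in 100% of runs at the preset correlation and in 0% with an estimated correlation.

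Alternatives were quantile normalization, one median per array, pseudocounts of 16 and 64, no filter or one at the 60th percentile, no variance trend, robust eBayes, probe sets ending in _at only, the replicate block and leaving out each array.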

Results

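Transcript levels were measured in leaf discs of Arabidopsis thaliana, accession Col-0, that had been kept for 1 h in the dark in MES buffer with or without 5 mM dithiothreitol (DTT), a membrane-permeant reductant of disulfide bonds. The discs came from full-grown source leaves harvested at the end of the night. The comparison asked how a shift of the cellular thiol redox state changes gene expression. Each group had 2 arrays from biological replicates, named here control 1 and 2 and DTT 1 and 2, and each array gave signals for 22810 probe sets. The trimmed mean signal was 100 on every array and the median lay between 25.4 and 32.8. With 2 arrays per group, their number limits the precision of every value below.

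The arrays separated first by replicate number. The hybridization control transcripts are added at fixed amounts to each labelled sample. Over their 9 probe sets, the median ratio was 1.88 for control 1 over control 2 and 1.74 for DTT 1 over DTT 2. The bioD-3 probe set ran the other way, at 0.949 and 0.850. For DTT over control the median ratio of the 9 was 0.998 in replicate 1 and 1.07 in replicate 2. Across the 13648 probe sets tested, which are not independent replicates, log2 signals correlated at 0.968 between control 1 and DTT 1 and at 0.972 between control 2 and DTT 2, against 0.919 between both controls and 0.885 between both DTT arrays. Replicate number was therefore treated as a processing batch. Counts over all probe sets and camera calls with all 4 arrays are given both without it and with it as a block. Counts of list members past the test are from the fit with the block. Without the block 0 members of any list passed, adjusted over all genes or over the list alone.

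Without the block, limma called 0 of 13648 probe sets changed by DTT at an adjusted p under 0.05, and 95 had an unadjusted p under 0.05. The smallest adjusted p was 0.9999. With the replicate block, limma called 126 probe sets, of which 39 were higher and 87 lower after DTT, and 1092 had an unadjusted p under 0.05. Of the 126, 112 changed at least 2-fold and 124 moved the same way in both replicates. Only 65 of the 126 belong to 1 named gene, and 57 have no gene in the annotation used. The block fit leaves 1 residual degree of freedom, and in simulated data of this design 11.0% of its calls were false, so its adjusted p-values are too small. The blocked count was 3 with no filter on low signals, 35 without the variance trend, 58 with a pseudocount of 16 and 71 with quantile normalization. The genes below are those called with the block. That choice was made after the fit without the block was seen to call none.

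With the replicate block, several genes of protein folding in the endoplasmic reticulum were called higher after DTT. ATERDJ3B, a DnaJ-type co-chaperone of the endoplasmic reticulum lumen, rose from a signal of 340.4 ± 153 to 1169 ± 682 (SD, n = 2), a 3.30-fold change (log2 1.72, SE 0.21, limma adjusted p = 1.68e-05). Its rise was 3.68-fold in replicate 1 and 2.96-fold in replicate 2. AT4G29520 rose 5.80-fold (adjusted p = 8.72e-08), by 6.50-fold and 5.17-fold in the replicates. CRT1b, a calreticulin of the lectin chaperone cycle, rose 2.07-fold (adjusted p = 0.0249), AT5G07340, a calnexin, 2.45-fold (adjusted p = 0.0074) and DER2.1, a Derlin of the degradation pathway for misfolded proteins, 2.02-fold (adjusted p = 0.0249). In replicates 1 and 2 the rise was 2.64-fold and 1.62-fold for CRT1b, 2.67-fold and 2.24-fold for AT5G07340, and 2.26-fold and 1.81-fold for DER2.1.

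Of the 33 genes listed beforehand for the unfolded protein response, 5 had a probe set of their own. Of these, 2 rose and 3 did not pass the test. When adjusted over the list alone, 4 were called higher. Among these was BZIP17, which rose in replicate 2 alone. BZIP60, a transcription factor of this response, had log2 changes of 0.81 and 0.54 in the replicates (adjusted p = 0.187), and BZIP17 had -0.11 and 2.99 (adjusted p = 0.145). BZIP28, of the same family, had -0.00 and -0.36 (adjusted p = 0.977). The list lay above the other genes in limma's camera test, with a median log2 change of 1.05 (adjusted p = 1.85e-04 without the block and 5.06e-08 with it). The call was lost with an estimated correlation (adjusted p = 0.492 without the block and 0.679 with it). In simulated data that setting called a shifted list of 30 genes in 0% of runs. Its losses, here and below, therefore cannot decide whether a list moved. The call was also lost without control 2 or without DTT 1. Such fits leave 1 array in a group and unbalance replicate number, so they mix the replicate difference with the response to DTT. The median was 0.81 in replicate 1 and 0.69 in replicate 2, 0.36 without DTT 1, 0.43 without control 2 and 1.74 without DTT 2. With pseudocounts of 16 and 64 it was 0.66 and 0.61.

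A wider list of 31 genes for translocation, folding and quality control in the endoplasmic reticulum was written after the probe annotation and the control probe sets had been read and before any gene was tested. It holds all 5 measured genes of the list above, so the calls of both lists are not independent. Of its members, 5 rose, ATERDJ3B and CRT1b of the list above among them, 0 fell and 26 did not pass the test. Its median log2 change was 0.44, with 0.77 in replicate 1 and 0.20 in replicate 2, and camera gave adjusted p = 9.54e-10 without the block and 1.35e-13 with it. With an estimated correlation the call was lost (adjusted p = 0.660 without the block and 0.746 with it). That leaves open whether the list moved, as said above. Fry did not call it either (adjusted p = 0.867 without the block and 0.571 with it). The median was 0.20 without DTT 1 and 0.66 without DTT 2, and camera called the list without each of the 4 arrays in turn.

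**Figure D1:**
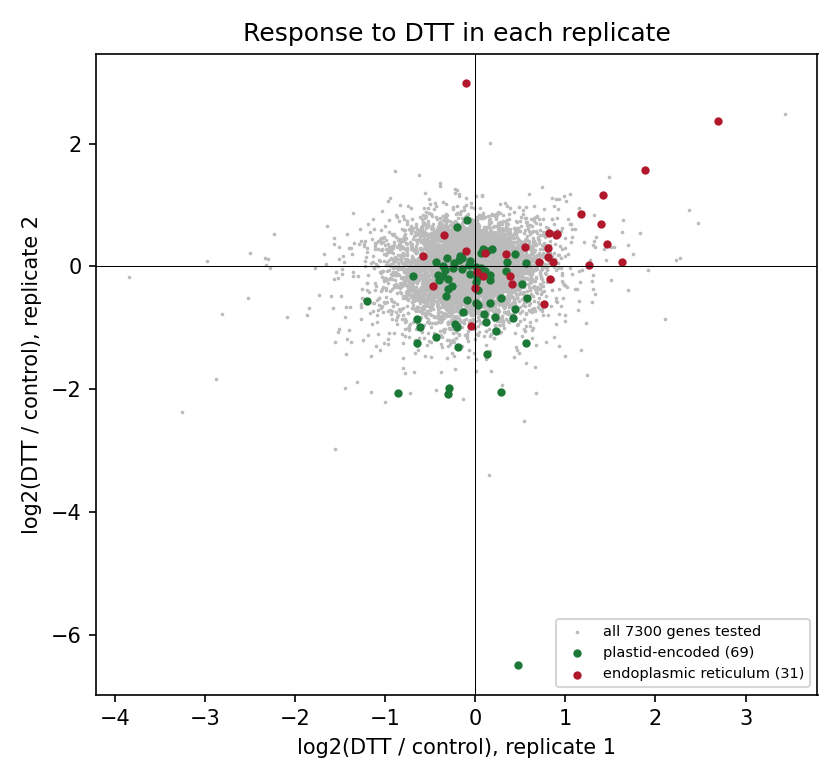
Log2 ratio of DTT over control in replicate 1 (x axis) and replicate 2 (y axis) for the 7300 genes tested, 1 point per gene, with plastid-encoded genes and genes of the endoplasmic reticulum coloured. The 31 endoplasmic reticulum genes have medians of 0.77 and 0.20 in replicates 1 and 2, and the 69 plastid-encoded genes have medians of -0.06 and -0.23.

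The largest rise among the 65 named probe sets called was that of AT4G34630, from 66.3 ± 15.8 to 514 ± 116 (SD, n = 2), or 7.77-fold (log2 2.96, SE 0.25, limma adjusted p = 2.54e-08). It rose 10.8-fold in replicate 1 and 5.58-fold in replicate 2. ZCF37 rose 3.14-fold, and GFAT, an enzyme of the hexosamine pathway, 3.02-fold, with 5.55-fold in replicate 1 and 1.64-fold in replicate 2. AT4G24110, AT5G47420, AT2G44660, AT1G66090 and AT5G52750 rose between 2.09-fold and 2.30-fold, and AT3G53670 rose 2.08-fold and 2.73-fold on its 2 probe sets. Within a replicate, the 12 largest rises ranged from 1.45-fold to 10.8-fold. Among probe sets with no gene in the annotation, the one with the largest rise rose 6.78-fold.

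Among named genes called with the block whose DTT arrays both lay below both control arrays, AT1G04770 had the largest fall. It is a relative of the sulfur-deficiency-induced gene SDI1. Its signal went from 322 ± 198 to 41.7 ± 9.33 (SD, n = 2), a 7.04-fold fall (log2 -2.81, SE 0.25, limma adjusted p = 5.20e-08), with falls of 9.56-fold and 5.18-fold in the replicates. The beta-glucosidase genes BGLU33 and BGLU40 fell 5.12-fold and 2.62-fold. AT1G51850, a leucine-rich repeat receptor kinase, fell 4.80-fold, with 2.93-fold in replicate 1 and 7.87-fold in replicate 2. Its signal of 4.5 on DTT 2 lay below the filter level. AT5G25450, a subunit of mitochondrial complex III, fell 3.28-fold, AT2G47550, a pectin methylesterase, 3.04-fold, and the glycosyltransferase gene UGT76E1 3.03-fold. AT5G47330 fell 3.05-fold, and AT5G12420, AT1G51620, AT1G74010 and AT1G22830 fell between 2.46-fold and 2.48-fold. Within a replicate, the 12 largest falls ranged from 2.00-fold to 9.56-fold. The probe set of smallest adjusted p, which has no gene in the annotation, fell 10.6-fold (adjusted p = 1.89e-09), with log2 changes of -3.39 and -3.41 in the replicates.

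**Figure D2:**
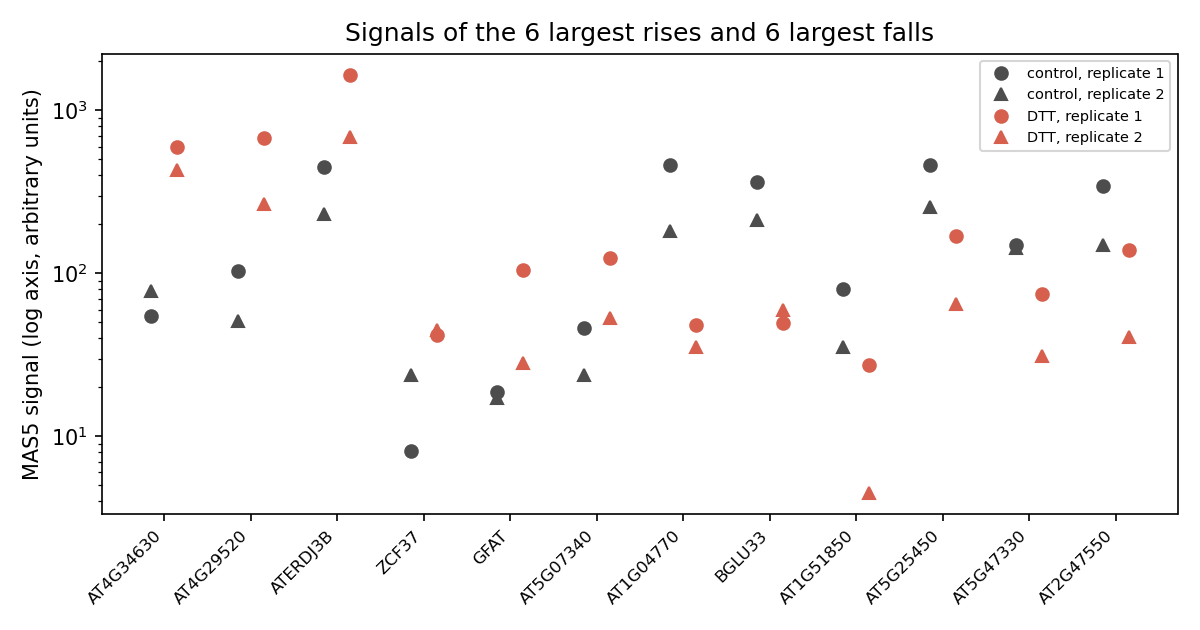
MAS5 signal on each array (y axis, log scale, arbitrary units) of the 6 genes with the largest rise and the 6 with the largest fall among genes called with the replicate block whose DTT arrays both lay beyond both control arrays. Each point is 1 array, with circles for replicate 1 and triangles for replicate 2. AT4G34630 went from a mean of 66.3 to 514 and AT1G04770 from 322 to 41.7.

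Early wound and elicitor genes had 3 measured members, none of which passed the test, and 2 were higher when adjusted over the list alone. WRKY53 had a log2 change of 0.76 (adjusted p = 0.167) and STZ, a zinc finger repressor, 0.55 (adjusted p = 0.268). WRKY6 had -0.24 (adjusted p = 0.955), with 0.23 and -0.72 in the replicates. Camera called the list with the block (adjusted p = 0.0300) and not without it (adjusted p = 0.0597) or with an estimated correlation (adjusted p = 0.679 with the block). The block call was lost with quantile normalization (adjusted p = 0.0632) and with no filter (adjusted p = 0.0546). Without the block the list was called with one median per array or log2(signal + 64) (adjusted p = 0.0473 in both) and without DTT 2 (adjusted p = 0.00532). Without DTT 1 the median was 0.24 and camera's direction was down (adjusted p = 0.983).

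With all 4 arrays, camera called no other list fixed beforehand, without the block (adjusted p from 0.53 to 0.832) or with it (adjusted p from 0.444 to 0.766). In the list of thiol and antioxidant enzymes, 0 of 11 measured members passed the test and the median log2 change was 0.10. The median was -0.27 without control 1, -0.15 without DTT 2, 0.34 without DTT 1 and 0.20 without control 2, and camera called the list higher in the last of these alone (adjusted p = 0.0303). TRXF2, a plastid thioredoxin, had 0.36 and GR1, a glutathione reductase, 0.24. In photosynthesis 0 of 6 passed, in sulfate assimilation 0 of 3 and in starch synthesis 0 of 3, with medians of -0.00, 0.12 and 0.15. APS4 and SIR of sulfate assimilation had 0.17 and 0.12, and the starch synthesis genes APL4 and SBE2.2 had 0.15 and 0.20. Lists with 1 or 2 measured members had no set test and no member past the fit. The glucosinolate and jasmonate lists had 1 measured member each, so adjusting over the list alone left its unadjusted p, which was under 0.05 in both. Over all probe sets tested, the limma adjusted p was 0.358 for BCAT4 and 0.294 for PDF1.2. BCAT4, of methionine chain elongation, had log2 changes of 0.38 and 0.85 in the replicates, while the signals of PDF1.2, a defensin, were 5.1 in control 1 and 0.9 in DTT 1, both below the filter level, and 311.3 in control 2 and 361.3 in DTT 2. The clock gene GI had -0.36, the starvation-list gene PPDK 0.25 and the hypoxia-list gene AT4G17260, a lactate dehydrogenase, 0.46. The reference genes AT2G28390 and AT4G34270 had log2 changes of -0.23 (SE 0.24) and 0.06 (SE 0.24). The guard cell marker FMA had 0.07, and no epidermis or phloem marker had a probe set of its own.

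The list of plastid-encoded transcripts was lower after DTT in the camera test with the replicate block (adjusted p = 1.17e-05), a call lost with an estimated correlation (adjusted p = 0.746) and without the block (adjusted p = 0.109). Of 69 measured, 4 fell and 65 did not pass the test. psbC, a core antenna protein of photosystem II, fell 2.74-fold (adjusted p = 3.81e-04), and psbB and psbN fell 2.28-fold and 1.93-fold. In replicates 1 and 2 the falls were 1.81-fold and 4.17-fold for psbC, 1.24-fold and 4.22-fold for psbB, and 1.57-fold and 2.39-fold for psbN. psaA had the largest mean fall of all named genes called, 8.07-fold (log2 -3.01, adjusted p = 0.0316), although its log2 change was 0.48 in replicate 1 and -6.50 in replicate 2. None of these 4 genes had both DTT arrays below both control arrays. The list had a median log2 change of -0.18, with -0.06 in replicate 1 and -0.23 in replicate 2. Among random lists matched on mean signal these replicate medians lay at percentiles 29.4 and 0. Leaving out an array unbalances replicate number, so the next medians mix the replicate difference with the response to DTT. In fits without the block, camera called the list higher without control 1 (median 0.26) and without DTT 2 (0.31). It was called lower without control 2 (-0.44) and without DTT 1 (-0.56). With all arrays and no block it was called lower with quantile normalization (adjusted p = 0.0250) and the stricter filter (adjusted p = 0.049998). The control probe set of 25S ribosomal RNA was lower after DTT, with log2 changes of -1.57 in replicate 1 and -2.04 in replicate 2. Its signal was 2525.6 on control 1 and 847.8 on DTT 1, against 100.5 on control 2 and 24.4 on DTT 2. It thus differed more between replicates than between treatments. That of 5S ribosomal RNA had -0.18 in replicate 1 and -2.81 in replicate 2, where its signals of 7 and 1 both lay below the filter level.

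The replicates overlapped in their largest changes more than independent lists would. At least 2-fold rises were seen for 156 probe sets in replicate 1, 82 in replicate 2 and 18 in both, against 0.94 for independent lists (Fisher's exact test, one-sided, p = 1.28e-18 across probe sets). At least 2-fold falls numbered 266, 314 and 37, against 6.12 (p = 7.74e-19 by the same exact test). Probe sets are not independent, so these p-values describe these arrays. Over all probe sets the log2 changes of the replicates correlated weakly, at 0.114.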

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

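Control probe sets of the array lay outside the comparison of the report, and 2 of the 36 above the filter level had both DTT arrays above both control arrays. If all 4 arrays were exchangeable, chance would give 16.7% in each direction, and 0 had both DTT arrays below. Of the 13648 other probe sets tested, 1093 had both DTT arrays above both control arrays and 1339 had both below. The middle GAPDH control probe set had a mean DTT signal of 440.4, with 473 and 407.9 against 359.6 and 396.4 in the controls. The 5' ubiquitin control probe set had a mean DTT signal of 2732, with 3155.8 and 2308.7 against 2147.8 and 2178.2. For 1 pair of probe sets per gene, the ratios of 3' to 5' control probe sets on control 1, DTT 1, control 2 and DTT 2 were 2.83, 1.59, 1.49 and 1.59 for ubiquitin, 5.94, 3.23, 2.72 and 4.07 for GAPDH, and 3.45, 2.64, 2.32 and 4.28 for actin. No explanation was tested for any of these.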

How the results depend on the processing

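Alternatives that join the replicate block with another choice were chosen after seeing the data. Lists beyond the 25 fixed beforehand were added after the control probe sets had been seen and before any gene was tested. Without a block the count of changed probe sets was 0 under every alternative except leaving out an array, where it ranged from 0 to 2 (2 without DTT 1, 0 higher and 2 lower, both at least 2-fold). With the replicate block it was 126, of which 39 were higher, 87 lower and 112 changed at least 2-fold. The labels do not say that numbers pair the samples, and leaving out an array with the block kept leaves 1 pair and no test. The blocked count was 71 with quantile normalization, 58 with log2(signal + 16), 35 without the variance trend and 3 with no filter on low signals, and 92 to 176 otherwise; the cause was not tested. All 126 kept their direction under each alternative joined with the block in which they were tested. Filters, eBayes settings and the choice of probe sets leave a log2 change as it is. Only the other scalings and the pseudocounts could therefore turn one. Without single arrays, 1 to 8 of those tested turned, psaA among them without DTT 2. Lists fixed beforehand and called by camera numbered 1, and 2 with one median per array, log2(signal + 64) or the replicate block, 0 with an estimated correlation or fry, and 0 to 2 without single arrays. Of the added lists 5 were called, 0 with an estimated correlation or fry, and 5 to 8 without single arrays. Leaving out an array also unbalances replicate number: the median turned sign for 13 of 23 lists, and 1 of the 6 called lists was called without each array. Among the 13 were plastid-encoded genes (-0.56 to 0.31; 0.26 without control 1 and 0.31 without DTT 2, both called higher; -0.44 without control 2 and -0.56 without DTT 1, both called lower), cytosolic ribosomal proteins (-0.12 to 0.37; -0.03 without control 1 and -0.12 without DTT 2, the latter called lower; called higher without control 2 or DTT 1), glutathione transferases (-0.33 to 0.43; -0.33 without DTT 2, called lower) and nuclear photosynthesis genes (-0.26 to 0.27; -0.26 without DTT 2, called lower; 0.27 without DTT 1 and 0.12 without control 2, both called higher). The other ranges of lists that turned were -0.97 to 0.19 for mitochondrion-encoded genes (called lower without control 2 or DTT 1), -0.42 to 0.48 for cytosolic chaperones (called higher without control 1 or DTT 2), -0.36 to 0.68 for starch synthesis, -0.27 to 0.34 for thiol and antioxidant genes (called higher without control 2), -0.26 to 0.23 for photosynthesis, -0.06 to 0.33 for redox enzymes (called higher without control 2), -0.11 to 0.19 for the proteasome, -0.27 to 0.09 for UDP-glycosyltransferases and -0.00 to 0.30 for histones. Signal over background limits the genes left out by the filter.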

Other observations

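Besides the endoplasmic reticulum list, camera without the block placed 4 of the 17 added lists apart, and with the block it called these 4 and the plastid-encoded list. Calcium and elicitor genes had a median log2 change of 0.26 over 20 members (adjusted p = 9.70e-04 without the block and 7.53e-04 with it), a call lost with an estimated correlation (adjusted p = 0.660 and 0.746). Losses with an estimated correlation leave open whether these lists moved. That setting called a list of 30 independent genes shifted by 0.4 in 0% of simulated runs, and lists of other sizes, shifts or correlations were not simulated. Fry called none of the added lists, without or with the block. The calcium and elicitor median was 0.34 and 0.17 in the replicates, and PUB24, a ubiquitin ligase, had 0.70. Cell wall loosening genes had -0.38 over 14 (adjusted p = 0.0102 and 0.0070), also lost with an estimated correlation (adjusted p = 0.680 and 0.753). The replicates had -0.45 and -0.04, and the expansin-like genes EXLA2 and EXLA1 had -0.55 and -0.44. The cell wall median shrank to -0.22 with a pseudocount of 16 and to -0.11 with one of 64. Glycolysis and fermentation genes had 0.24 over 10 (adjusted p = 0.0102 and 0.0070, or 0.660 and 0.746 with an estimated correlation), with 0.18 and 0.22 in the replicates. Cytosolic ribosomal protein genes had 0.11 over 99 (adjusted p = 0.0102 and 0.00655, or 0.690 and 0.825 with an estimated correlation). The replicates, at -0.01 and 0.26, differed in sign, and the median was -0.03 without control 1 and -0.12 without DTT 2, where camera called the list lower (adjusted p = 0.0215). Fits without 1 array unbalance replicate number, so their calls and losses mix the replicate difference with the response to DTT. Leaving out DTT 1 ended the calls of the calcium and elicitor, cell wall and glycolysis lists. The cell wall call was also lost without control 2, and the glycolysis call without control 1 and without DTT 2. Without and with the block, the ribosomal call was lost with quantile normalization (adjusted p = 0.132 and 0.0899), and the stricter filter ended the cell wall call (adjusted p = 0.0657 and 0.0563) and the glycolysis call (adjusted p = 0.0686 and 0.0747). With no filter the cell wall call was lost without the block (adjusted p = 0.107). No single member of these lists passed the fit. The following lists were not called with all arrays and the 40th percentile filter without the block (adjusted p from 0.0723 to 0.833) or with it (adjusted p from 0.0795 to 0.648): median log2 changes were 0.09 for cytosolic chaperones, 0.11 for redox enzymes, 0.06 for glutathione transferases, -0.19 for UDP-glycosyltransferases, 0.02 for nuclear photosynthesis genes, 0.06 for iron and zinc genes, 0.14 for respiration, 0.04 for the proteasome, -0.21 for sugar transporters of the SWEET family and 0.18 for histones and cell cycle genes. With no filter on low signals camera called respiration higher without and with the block (adjusted p = 0.0368 and 0.02005) and redox enzymes higher with it (adjusted p = 0.0414). Leaving out 1 array gave calls for redox enzymes (higher without control 2, adjusted p = 0.0169), cytosolic chaperones (higher without control 1 or DTT 2, adjusted p = 0.0226 and 0.00329), glutathione transferases (lower without DTT 2, adjusted p = 0.0178) and nuclear photosynthesis genes (higher without DTT 1 or control 2, adjusted p = 0.00189 and 0.049953, and lower without DTT 2, adjusted p = 0.0107).

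The test of the spread between replicates and that of scaling for the plastid list were chosen after the values had been seen. For the latter, the bound first written, a median below -0.3, lay beyond the unscaled median of -0.18 and could not decide. The other tests were written before the list medians were computed, though the values of the highest ranked probe sets, ATERDJ3B, AT4G29520 and psbC among them, and of ribosomal RNA had been seen.

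Camera placed the list of 31 endoplasmic reticulum genes higher after DTT, and 26 members did not pass the test. The call was lost with an estimated correlation (adjusted p = 0.660), and fry did not call the list (adjusted p = 0.867). The estimated correlation called a list of 30 independent genes shifted by 0.4 in 0% of simulated runs. Its loss therefore leaves open whether the list moved. The list stayed higher under quantile normalization, at a median of 0.45, so array differences of the kind it removes did not account for it. One median per array shifts all genes of an array alike, so the median of 0.46 under that scaling could not decide. One replicate alone did not account for the higher list: its median lay at percentile 100 of matched random lists in replicate 1 and 98.8 in replicate 2. A response of these genes to DTT remains a possible explanation. For single genes it rests on the 5 members called with the block, and no mechanism was tested.

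Camera with the replicate block placed plastid-encoded transcripts lower after DTT, with 65 of 69 members short of the test. The list median lay at percentile 29.4 of matched random lists in replicate 1 and 0 in replicate 2. Taken 1 at a time, only replicate 2 thus set the list apart. The list was not called without the block (adjusted p = 0.109). It was also not called with the block and an estimated correlation (adjusted p = 0.746), a setting that called a shifted list in 0% of simulated runs. The median turned to 0.26 and 0.31 without control 1 and DTT 2, where camera without the block called the list higher. Without control 2 and DTT 1 it was called lower. Leaving out an array unbalances replicate number, so these turns cannot be told apart from the difference between replicates. Less labelling of RNA without a poly(A) tail in the DTT samples is a candidate explanation of the lower call. The mitochondrial transcripts, which also mostly lack such a tail, had a median log2 change of -0.40, with -0.28 and -0.31 in the replicates. Camera did not call them without the block (adjusted p = 0.173) or with it (adjusted p = 0.0746). With the block they were called lower under log2(signal + 64), where the median was only -0.10 (adjusted p = 0.0382). They were also called lower with the stricter filter, with a median of -0.54 over 5 genes (adjusted p = 0.0489). In fits without the block they were called lower without control 2 (-0.90) and DTT 1 (-0.97). They were not called without control 1 (0.19) or DTT 2 (-0.04). In replicate 1 the plastid median was only -0.06 while 25S ribosomal RNA had -1.57. With the block, camera still called the list under quantile normalization, at a median of -0.18 (adjusted p = 1.09e-06). Array differences of the kind it removes thus did not account for the call. One median per array shifts all genes of an array alike, and camera compares the list with the other genes. The median of -0.16 under that scaling (camera adjusted p = 1.06e-05) therefore could not decide. A response of organelle transcripts to DTT was not tested.

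The probe sets called with the replicate block could come from spread between the replicates' own responses. The difference of the replicates' log2 changes, times 0.5, holds no shared response. Over all 13648 probe sets tested it was at least 1 in size for 70, against 159 for the mean of both changes. Spread of this kind thus does not account for all of the large mean changes, and may account for a part. The counts do not cover the 126 called probe sets on their own, so they cannot say how many of those it explains.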
